A study of Mus musculus with 15 samples.

How the data were processed

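The series holds 15 Affymetrix Mouse Genome 430 2.0 arrays of sorted mouse XCR1+ dendritic cells in 5 groups of 3: thymus CCR7-, thymus CCR7+, spleen CCR7-, spleen CCR7+ from untreated mice, and spleen CCR7+ from mice given 10 µg polyI:C intraperitoneally 18 h earlier. The sort gates in the labels are CD11c+ CD317- CD172a- with CD117+ CCR7- for immature and CD117- CCR7+ for mature cells. Per the submitters' processing notes the deposited values are log2 RMA values made by the authors with RMA and the affy package, whose versions are not given in the sources used here. Their notes do not state which arrays were normalised together. The deposited values ran over a range typical of log2 signals with near-equal medians (4.86 to 5.00 per array). RMA gives no detection calls, so dim signal cannot be told from background for a single probe set, and fold changes of genes near background are compressed.

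The table had 45101 probe sets. Of these 34958 carried exactly 1 gene symbol, 932 carried several and 9211 were not listed in the probe annotation used. The probe sets with 1 symbol covered 18195 genes, and each gene was represented by its probe set with the highest mean over all 15 arrays. Genes were tested when their value exceeded the 40th percentile of all values (4.39) in at least 3 arrays, which left 13629 tested genes. Differences were tested with limma 3.58.1 in R 4.3.3, with a model of 5 group means fitted to all 15 arrays, contrasts and moderated variances (eBayes, 10 residual degrees of freedom and 4.01 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and calls at least 2-fold apart were counted as well. Changes are log2 fold changes, CCR7+ minus CCR7-, polyI:C minus untreated or thymus minus spleen, and the difference between tissues is the thymus change minus the spleen change. Values without a unit in brackets after a gene are these log2 fold changes. The 7 comparisons and their tests were fixed before the data were examined.

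Similarity of maturation changes was measured with Pearson's r, Spearman's rho and covariance across genes, and with the number of genes called in both. Each was set beside 100 simulations in which the residuals of the arrays were permuted with random signs under unchanged groups. Simulated unchanged groups gave a median overlap of 0 called genes. In all, 31 gene lists (550 of 608 entries had a probe set) were written before the data were examined, 21 for biological programmes, 9 for other cell types and 1 for handling stress. They were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over the lists within each comparison. For each list the members called over all genes and those called when adjusted over the list alone were counted.

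The genes named were chosen by a rule fixed before the data were examined. For each comparison these were the 8 largest rises and 8 largest falls (5 and 5 between tissues and for the difference between tissues) among genes called, at least 2-fold apart and with all 3 arrays of one group above all 3 of the other; this last condition was not applied to the difference between tissues. Symbols of predicted or unnamed genes were left out. To these were added up to 3 rising and 3 falling called members of each list, and the sorting markers. A gene named for 1 comparison was given its values in others where useful. The rule chose 683 called pairs of gene and comparison, apart from the sorting markers, and 263 of these are printed. Pairs whose calls ended when single arrays were left out were mostly not printed, and they made up 129 of the 420 left out.

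The model and the calls were tested on simulated data drawn from each gene's mean and residual spread. Of 200 genes given a change, 68% of those at 2-fold and 98% of those at 4-fold were called, and 9 of 175 calls were false. In these data each of the 13629 genes varied on its own, with the same spread in all groups. In the arrays genes vary together, the spread differed between groups and far more genes were called, so these rates need not hold there. The alternatives tried were no filter on dim probe sets and a 60th percentile filter, the mean of a gene's probe sets, the probe set of largest variance, probe sets ending in _s_at, _x_at or _a_at left out, quantile normalisation repeated, centring on array medians, eBayes with an intensity trend and robust settings, array weights, a fit of the compared groups only, the replicate number as a block, a test against a log2 fold change of 1 (treat), and leaving out each array in turn. The replicate numbers of the titles appear in every group, and nothing in the labels says whether they mark shared mice or days. The sample descriptions carry other codes, whose numbers differ from those of the titles and whose meaning is not stated. The numbers of the titles were used for the replicate block and the correlations below. The correlation of arrays with the same number, after removing group means, exceeded 0.1 for all 3 numbers only between the tissues, with 0.57, 0.52 and 0.56 for CCR7- cells and 0.46, 0.42 and 0.59 for CCR7+ cells. For those comparisons 6 of 6 arrays were closest to the array of their own number. Between polyI:C and untreated spleen CCR7+ cells the correlations were 0.00, 0.64 and 0.14 for numbers 1 to 3. Tables were prepared with Python 3.11.15 (pandas) and figures drawn with matplotlib 3.10.9.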

Results

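XCR1+ dendritic cells (DCs) of mouse thymus and spleen were compared as immature (CCR7-) and mature (CCR7+) sorted cells. XCR1 is in the name of the samples but not among the sort gates given. Whether both fractions hold the same kind of DC was not tested, so a change called maturation can include a difference in the cells sorted. The question behind the arrays was how far maturation in the thymus resembles maturation in the untreated spleen, and how both compare with spleen CCR7+ cells taken 18 h after 10 µg polyI:C. Ccr7 and Kit transcripts followed the gates that set the fractions apart. Ccr7 averaged 8.84 and 13.03 (log2) in thymus CCR7- and CCR7+ cells, and 8.42 and 12.95 in the same fractions of untreated spleen. Kit fell from 10.68 to 8.16 in thymus and from 11.25 to 8.61 in spleen. The gates on CD11c (Itgax), CD317 (Bst2) and CD172a (Sirpa) were the same in all groups, but the transcripts of Itgax and Bst2 were not level. Itgax averaged 9.43 and 6.31 in thymus CCR7- and CCR7+ cells, 9.80 and 8.62 in untreated spleen and 5.92 after polyI:C. Bst2 averaged 10.35 and 10.88 in thymus, 8.51 and 9.21 in untreated spleen and 11.93 after polyI:C. None of the sorting transcripts is a finding between the fractions. Of 13629 genes tested with limma, between 4969 and 6329 were called in each of the 3 maturation comparisons. These were 37.3% of genes in thymic, 36.5% in homeostatic and 46.4% in polyI:C maturation. For polyI:C against untreated CCR7+ cells 18.2% were called, and 8.2% between immature and 12.2% between mature cells of the tissues. A list count near such a share is no result about the list. Each group had 3 arrays, which limits the precision of every fold change. An exact test of 3 arrays against 3 cannot give a p-value below 0.1, and for each gene 10% of such comparisons separate the groups completely by chance. The origin of the replicates (mice, pools or sort days) is not stated, so the adjusted p-values measure the spread between these samples only.

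In the thymus, most DC maturation and NF-kB genes and 14 of 22 T cell ligands were higher in CCR7+ than in CCR7- cells, and cell cycle and most XCR1+ DC identity genes were lower. Camera called these 5 lists, and with an estimated correlation none of the calls held (adjusted p from 0.115 to 0.271). The largest rises were those of Cdh2, Insm1, Ndnf, Arg2, Stat4, Ccl5, Pygl and Oprd1, with log2 fold changes from 6.31 (Cdh2) to 5.68 (Oprd1). Cd244a, Slamf8, P2ry14, Tlr3, Rgs18 and P2ry6 were among the genes with the largest falls, and Tlr3 changed by -5.70 (standard error 0.49, adjusted p = 5.3e-07). In all, 2293 genes were higher and 2786 lower in CCR7+ cells, 1283 and 1612 of them at least 2-fold.

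Most DC maturation genes rose in the thymus. Of 21 tested, 19 rose, 1 fell and 1 was not called (20 and 1 adjusted over the list alone), with a median log2 fold change of 2.80 and rises of 4.30 for Il15ra and 4.22 for Tnfrsf4. NF-kB genes rose in 18 of 19 cases and none fell, led by Relb (3.21), Birc2 (3.07) and Rel (2.04); adjusted over the list alone the number was also 18. Among the genes listed for T cell costimulation and inhibition, Jag1 (4.91), Cd70 (4.86), Cd274 (3.95) and Cd80 (1.59) rose, while Havcr2 (-4.72) and Btla (-2.71) fell. Of these genes 14 of 22 were higher and 5 lower (14 and 6 adjusted over the list alone). They are called T cell ligands here, though some, such as Havcr2 and Btla, are themselves receptors. Genes associated with tolerance rose in 12 of 20 cases and fell in 3, the same numbers adjusted over the list alone, with Arg2, Itgb8 (5.36) and Tgfb2 (2.97) among the rises. Il15 (3.34) and Il12b (2.47) rose among the cytokines and Il18 fell (-3.24), so that 7 of 18 were higher and 2 lower, adjusted over the list alone also 7 and 2. Cxcl1 (4.33) and Ccl22 (2.29) rose and Cxcl9 fell by 4.20. Of 16 chemokines, 6 rose and 3 fell (8 and 3 adjusted over the list alone).

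Most XCR1+ DC identity genes and all cell cycle genes tested fell in thymic CCR7+ cells. Of 23 identity genes 19 fell, among them Naaa (-5.34), Tlr3 and Cd36 (-4.65), whereas 3 rose, including Batf3 (0.93) and Ly75 (0.90); the numbers were the same adjusted over the list alone. Every one of the 28 cell cycle genes tested fell, adjusted over the list alone also 28, with Ccnb2 (-3.81), Tk1 (-3.75) and Cdc6 (-3.72) among the larger falls. In antigen presentation by MHC class II, Marchf1 (-4.26) and H2-DMa (-2.71) fell and Lgmn (3.25) rose, with 6 of 14 genes lower and 2 higher (9 and 2 adjusted over the list alone). Uptake receptors and Toll-like receptors lost Cd207 (-4.63) and Myd88 (-1.70) and gained Irak3 (2.00). Of 19 uptake receptors 6 fell and 4 rose, and of 18 Toll-like receptor genes 8 fell and 1 rose; the counts were 6 and 4, and 9 and 1, adjusted over the list alone.

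Other programmes in the thymus had a part of their members called, in several lists near the 37.3% called of all genes. Glycolysis genes fell in 7 of 16 cases and rose in 3, also 7 and 3 adjusted over the list alone, with Hk2 (-3.70) and Ldha (-2.47) against Pfkfb3 (3.23). ER stress and secretion genes fell in 13 of 18 cases, led by Creld2 (-3.08), and rose in 3 (13 and 4 adjusted over the list alone). Of 26 genes of oxidative phosphorylation 9 fell and none rose, as they did adjusted over the list alone. Bcl2l14 (3.11) and Fas (2.51) were among the rises in apoptosis regulators, of which 8 of 16 rose and 2 fell (9 and 2 adjusted over the list alone). Anxa3 rose by 4.59 among cytoskeleton and migration genes, where 10 of 24 were higher and 2 lower, with the same numbers adjusted over the list alone. MHC class I genes rose in 5 of 16 cases and fell in 2, cholesterol synthesis genes rose in 6 of 18 and fell in 5, and cholesterol efflux genes rose in 5 of 12 and fell in 2. Adjusted over the list alone these were 5 and 2, 7 and 5, and 5 and 2. Of 28 type I interferon response genes 4 rose, including Herc6 (2.00) and Ifit1 (1.49), and 11 fell, and of 15 interferon gamma response genes Gbp2 (5.11) rose with 3 others while 3 fell. Adjusted over the list alone the numbers were 5 and 11, and 4 and 4.

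Homeostatic maturation in the spleen repeated much of this picture. Its largest falls were smaller than those in thymus, though more genes were lower (3291 against 2786). Zmynd15, Insm1, Jag1, Ankrd33b, Dscaml1, Asprv1, Ccl5 and Anxa3 rose most, from 6.59 for Zmynd15 to 5.83 for Anxa3. Serpinb2 (-3.54), Rgs18 (-3.34), Hcls1 (-3.30), Slamf8 (-3.28), Iqgap2 (-3.16) and Tlr3 (-3.14) were among the largest falls. In all, 1678 genes were higher and 3291 lower, 889 and 1784 of them at least 2-fold. Of 21 DC maturation genes 18 rose, among them Socs2 (5.08) and Tnfrsf4 (4.68), and 2 fell (19 and 2 adjusted over the list alone). The 2 that fell were Cd86 (-1.15) and Cd80 (-0.82). The 4 probe sets of Cd80 ran from -1.23 to 0.14. The call for Cd80 ended without spleen CCR7- replicate 2 (-0.70) and without spleen CCR7+ replicate 1 (-0.53), and in a fit of the compared groups only (-0.82). NF-kB genes rose in 18 of 19 cases, also 18 adjusted over the list alone, with Relb at 3.08 and Birc2 at 3.07.

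Several cytokine and chemokine genes rose in the untreated spleen. Il15 rose by 3.22, Il12b by 3.14, Lta by 2.15, Cxcl1 by 4.37 and Ccl22 by 3.99. Of 18 cytokines 8 rose and 2 fell, and of 16 chemokines 7 rose and 2 fell; adjusted over the list alone these were 8 and 2, and 8 and 3. Among T cell ligands Cd70 (4.37), Pdcd1lg2 (2.88) and Cd274 (2.03) rose and Havcr2 (-2.69) and Btla (-1.99) fell, and of 22 tested 11 rose and 8 fell, also 11 and 8 adjusted over the list alone. Arg2 (5.56) led the genes associated with tolerance, of which 11 of 20 rose and 2 fell, with the same numbers adjusted over the list alone. Identity genes fell in 19 of 23 cases and rose in 4 (also 19 and 4 adjusted over the list alone), with a median of -1.74 and a fall of 2.69 for Rab7b. Aurkb (-2.70) and Mcm7 (-2.69) showed the largest falls of the cell cycle genes, of which 26 of 28 fell (27 adjusted over the list alone).

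Many cholesterol synthesis genes rose in the spleen. Idi1 (2.45), Fdft1 (2.28), Hmgcs1 (2.12) and Insig1 (1.12) were among 13 of 18 genes that were higher, with 2 lower (15 and 3 adjusted over the list alone) and a median of 0.97. The list's camera adjusted p = 2.19e-06, and adjusted p = 0.0791 with an estimated correlation. In the MHC class II list, H2-Ob (-2.35), Ciita (-2.12) and Marchf1 (-2.52) fell and Lgmn rose (1.93); 6 of 14 fell and 3 rose (8 and 3 adjusted over the list alone). The interferon response was mixed, with Herc6 (2.79), Oasl1 (2.25) and Usp18 (1.98) higher and Irf7 lower (-1.48), so that 8 of 28 rose and 5 fell (10 and 5 adjusted over the list alone). Among the other programmes, glycolysis fell in 8 of 16 genes and rose in 2 (9 and 2 adjusted over the list alone), oxidative phosphorylation fell in 11 of 26 and rose in 2 (13 and 2), and ER stress and secretion fell in 11 of 18 and rose in 4 (11 and 4). Apoptosis regulators rose in 8 of 16 cases and fell in 3 (8 and 3 adjusted over the list alone), and cytoskeleton genes rose in 10 of 24 and fell in 3 (11 and 3). MHC class I genes rose in 5 of 16 cases and fell in 1 (5 and 1 adjusted over the list alone), Toll-like receptor genes fell in 8 of 18 and rose in 2 (8 and 2), and uptake receptors fell in 6 of 19 and rose in 2 (6 and 2). Interferon gamma response genes fell in 7 of 15 cases and rose in 3 (7 and 3 adjusted over the list alone), and cholesterol efflux genes rose in 2 of 12 and fell in 2 (2 and 2). Spleen CCR7+ replicate 1 decided some of the small counts. Without it 1 gene fell in each of the DC maturation, cytokine, chemokine, tolerance, cholesterol synthesis and cytoskeleton lists, no oxidative phosphorylation gene rose and 3 cholesterol efflux genes rose.

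Thymic and splenic homeostatic maturation were alike in direction for nearly every gene called in both. Arg2, Ccl5, Insm1, Il15, Relb, Birc2 and Cd70 rose by similar amounts in both tissues, and Tlr3, Slamf8, Rgs18, Havcr2 and Marchf1 fell in both. Of 3590 genes called in both, 1353 were higher in both and 2202 lower in both, against 282 and 673 for independent calls. In opposite directions were 35 genes, against 897 for independent calls, so that 99.0% had the same sign. Across the 13629 genes the log2 fold changes correlated with Pearson's r = 0.844 and Spearman's rho = 0.772, and genes are not independent replicates. The covariance was 0.783, and in 100 simulations of unchanged groups it averaged 0.002 and was at most 0.07, while r reached up to 0.635. No arrays were shared between these comparisons, but arrays with the same replicate number resembled each other between the tissues. The simulations did not keep this link, so they can understate the similarity that unchanged groups would give. All 3 maturation comparisons, polyI:C included, had 1158 genes higher and 1954 lower in common.

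**Figure D1:**
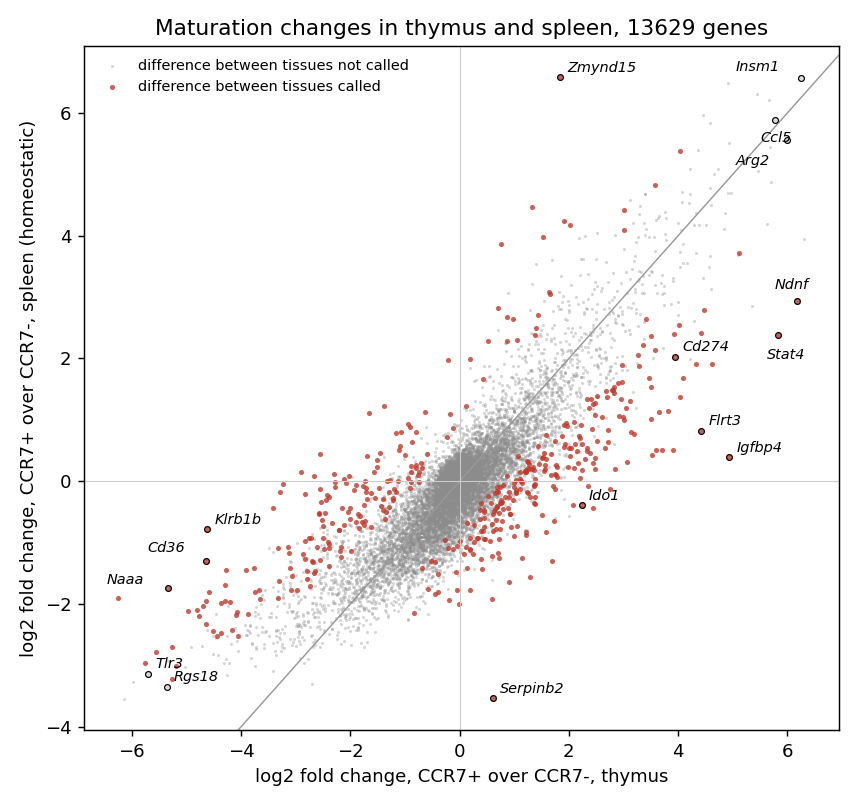
Log2 fold change of CCR7+ over CCR7- cells in thymus (horizontal) and untreated spleen (vertical) for 13629 genes, with the 433 genes whose change differed between the tissues in red and the line of equal change in grey. Insm1, Arg2 and Ccl5 lie near the line, while Igfbp4 (4.93 in thymus) and Zmynd15 (6.59 in spleen) lie far from it.

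Where the tissues differed, the thymus usually showed the larger change. Igfbp4 rose by 4.93 in thymus, and its change there exceeded that in spleen by 4.54 (standard error 0.36, adjusted p = 1.5e-05). Its 6 probe sets above the filter gave differences from -0.29 to 4.54, none called negative, so the value given is the highest. Flrt3 (difference 3.60), Ramp3 (3.40), Stat4 (3.44) and Ndnf (3.24) also rose more in thymus. Falls were larger in thymus for Cd244a (-4.34), Naaa (-3.59), Cd36 (-3.36), P2ry14 (-2.79), Rab7b (-2.57) and Cd207 (-2.32). The call for the Naaa difference ended with the probe set of largest variance (-3.02). For Klrb1b (-3.83) and Mgl2 (-2.12), which fell in thymus, and Serpinb2 (4.14), which fell in spleen, the CCR7- cells of the other tissue were near or below the filter value of 4.39, so that a fall there could not be seen. Zmynd15 went the other way, with a rise of 1.84 in thymus and 6.59 in spleen (difference -4.74), from CCR7- means of 10.95 and 4.70. In all, 244 genes had a more positive change in thymus and 189 a more negative one, 202 of the 244 among genes that rose in thymus and 161 of the 189 among genes that fell there. The counts depended on single arrays. Without thymus CCR7- replicate 3 they were 143 and 120, without thymus CCR7- replicate 2 the more positive ones were 156, without thymus CCR7+ replicate 2 they were 145, without thymus CCR7+ replicate 3 they were 158 and the more negative ones 125, and without spleen CCR7- replicate 3 the more positive ones were 159. With array weights the more negative ones were 284.

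Immune ligands and interferon genes were among the differences. Cd80 (2.41) and Ido1 (2.62) changed more positively in thymus, where Cd80 rose by 1.59 and Ido1 by 2.23. In spleen Ido1 was not called (-0.39). The 4 probe sets of Cd80 gave differences from -0.35 to 3.05, none called negative. Gbp2 (1.38) also had a more positive change in thymus. Usp18 (-2.20) and the chemokines Cxcl9 (-2.24) and Ccl9 (-2.44) had a more negative one, as did Insig1 (-1.75) of the cholesterol genes and H2-DMa (-1.40). Cd274 rose by 3.95 in thymus and 2.03 in spleen (difference 1.92, adjusted p = 0.027). That call ended without spleen CCR7- replicate 2 (1.85) or 3 (1.89), thymus CCR7- replicate 2 (1.92) or 3 (1.86), or thymus CCR7+ replicate 1 (1.86), 2 (1.96) or 3 (1.94). Among 23 identity genes 10 fell more in thymus and none less, and adjusted over the list alone 14 fell more. In the camera test the list's adjusted p = 2.97e-11, and adjusted p = 0.152 with an estimated correlation. Of the 18 cholesterol synthesis genes 4 had a more negative change in thymus (9 adjusted over the list alone), of the 28 interferon response genes 5 did (10 adjusted over the list alone), and of the 28 cell cycle genes 1 did (3 adjusted over the list alone). Without spleen CCR7+ replicate 1 these 3 counts were 5, 3 and 0.

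**Figure D2:**
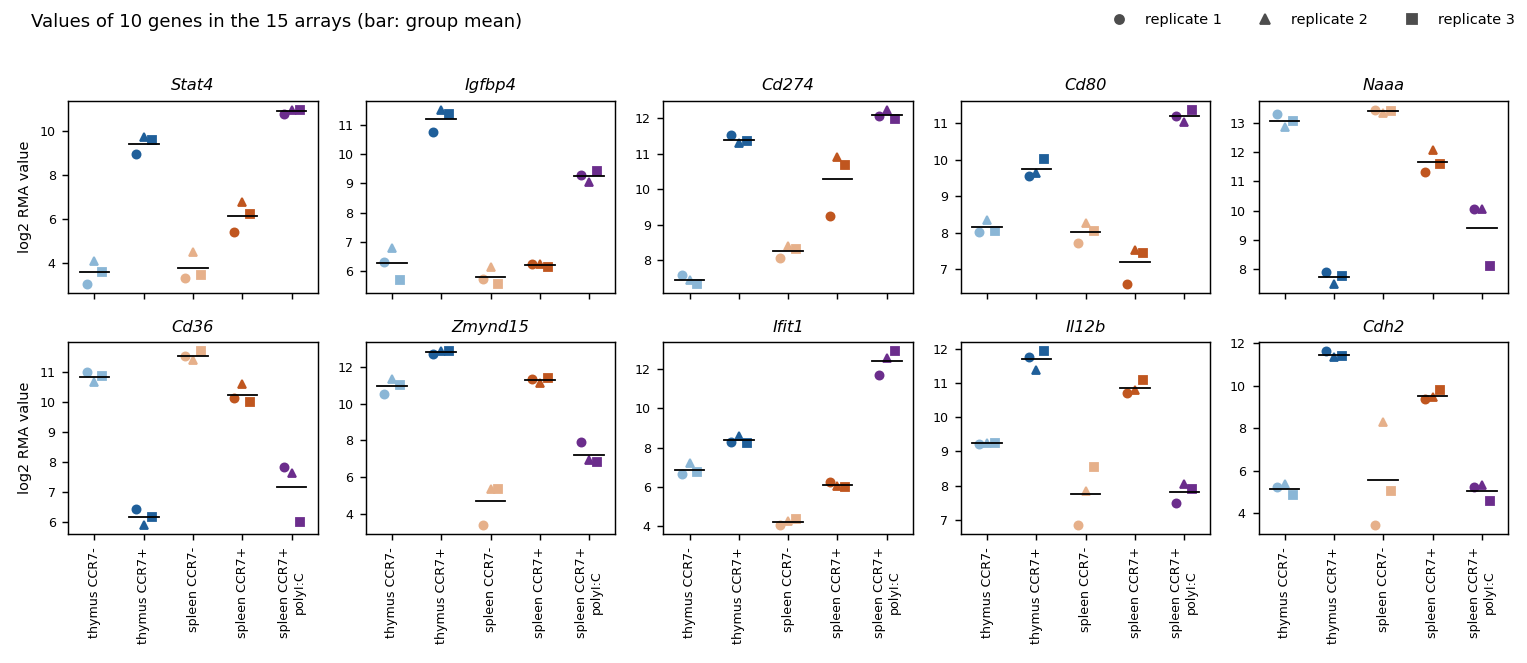
Log2 RMA values of 10 genes in each of the 15 arrays by group, with symbols for the replicate number and bars for the group mean. Stat4 and Igfbp4 rose far more in thymus than in untreated spleen, Zmynd15 started from a mean of 10.95 in thymus CCR7- cells and 4.70 in spleen CCR7- cells, and Ifit1 was highest after polyI:C.

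PolyI:C maturation in the spleen changed many of the same genes and raised interferon response genes. Ifit1 (8.19), Stat4 (7.14), Arg2 (6.40), Asprv1 (6.38), Rtp4 (6.33), Oasl2 (6.30), Oasl1 (6.15) and Ccl5 (6.13) were among the largest rises against untreated spleen CCR7- cells. Hepacam2 (-6.28), Slc9a9 (-5.77), Gpr34 (-5.42), Havcr2 (-5.10), Itga8 (-4.98), Egr3 (-4.91), Ptpre (-4.79) and H2-Ob (-4.77) fell most. In all, 2508 genes were higher and 3821 lower, 1307 and 2463 at least 2-fold. Of 28 type I interferon response genes 27 rose and none fell, also 27 adjusted over the list alone, with a median of 3.81. The list's camera adjusted p = 1.83e-20, and adjusted p = 0.0803 with an estimated correlation. No CCR7- cells from treated mice were measured, so these changes mix maturation with the treatment itself.

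Most DC maturation and NF-kB genes also rose after polyI:C. Of 21 DC maturation genes 18 rose and none fell, with Tnfrsf4 (5.24), Socs2 (5.22) and Cd80 (3.19) higher, and of 19 NF-kB genes 17 rose, including Birc2 (3.93) and Relb (3.39); adjusted over the list alone the numbers were also 18 and 17. Cd70 (5.59) and Pvr (4.47) led 15 of 22 T cell ligands that rose, against 5 that fell, also 15 and 5 adjusted over the list alone. Il15 (3.74), Il6 (3.14), Osm (3.10) and Cxcl10 (3.01) rose, while Ccl3 fell (-3.03). Il12b, which rose in thymus and untreated spleen, was not called (0.07), and neither was Cdh2 (-0.53). Of 18 cytokines 9 rose and 2 fell and of 16 chemokines 8 rose and 4 fell, with the same numbers adjusted over the list alone. Genes associated with tolerance rose in 14 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone).

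Identity genes fell by a median of 3.29 after polyI:C, with 18 of 23 lower, among them Gcsam (-4.38) and Cd36 (-4.36), and 2 higher, also 18 and 2 adjusted over the list alone. Ciita (-4.11) and Marchf1 (-3.91) fell and Lgmn rose (4.41) in the MHC class II list, where 9 of 14 fell and 3 rose (10 and 3 adjusted over the list alone), while 10 of 16 MHC class I genes rose and none fell, also 10 adjusted over the list alone. Oxidative phosphorylation fell in 18 of 26 genes (19 adjusted over the list alone), with Ndufv1 at -1.85 and Ndufs3 at -1.81. Cell cycle genes fell in 22 of 28 cases, such as Mcm6 (-2.09) and Mcm2 (-2.07), and only Ccne1 rose (2.46); adjusted over the list alone 24 fell and 1 rose. Egr2 (-3.85), Nr4a1 (-3.29) and Egr1 (-2.61) were among 9 of 18 handling stress genes that fell, also 9 adjusted over the list alone. Axl (3.25) and Clec7a (2.82) rose among the uptake receptors, of which 9 of 19 fell and 4 rose (9 and 4 adjusted over the list alone). Toll-like receptor genes fell in 8 of 18 cases and rose in 3 (10 and 3), interferon gamma response genes rose in 7 of 15 and fell in 2 (8 and 2), and glycolysis genes fell in 10 of 16 and rose in 2 (10 and 3), the last pairs each adjusted over the list alone. Apoptosis regulators rose in 9 of 16 cases and fell in 1 (9 and 1), cytoskeleton genes rose in 10 of 24 and fell in 3 (10 and 3), and ER stress genes fell in 11 of 18 and rose in 4 (11 and 4), in the same order. Cholesterol synthesis rose in 4 of 18 genes and fell in 3 (4 and 3 adjusted over the list alone), and efflux rose in 4 of 12 and fell in 3 (5 and 5).

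**Figure D3:**
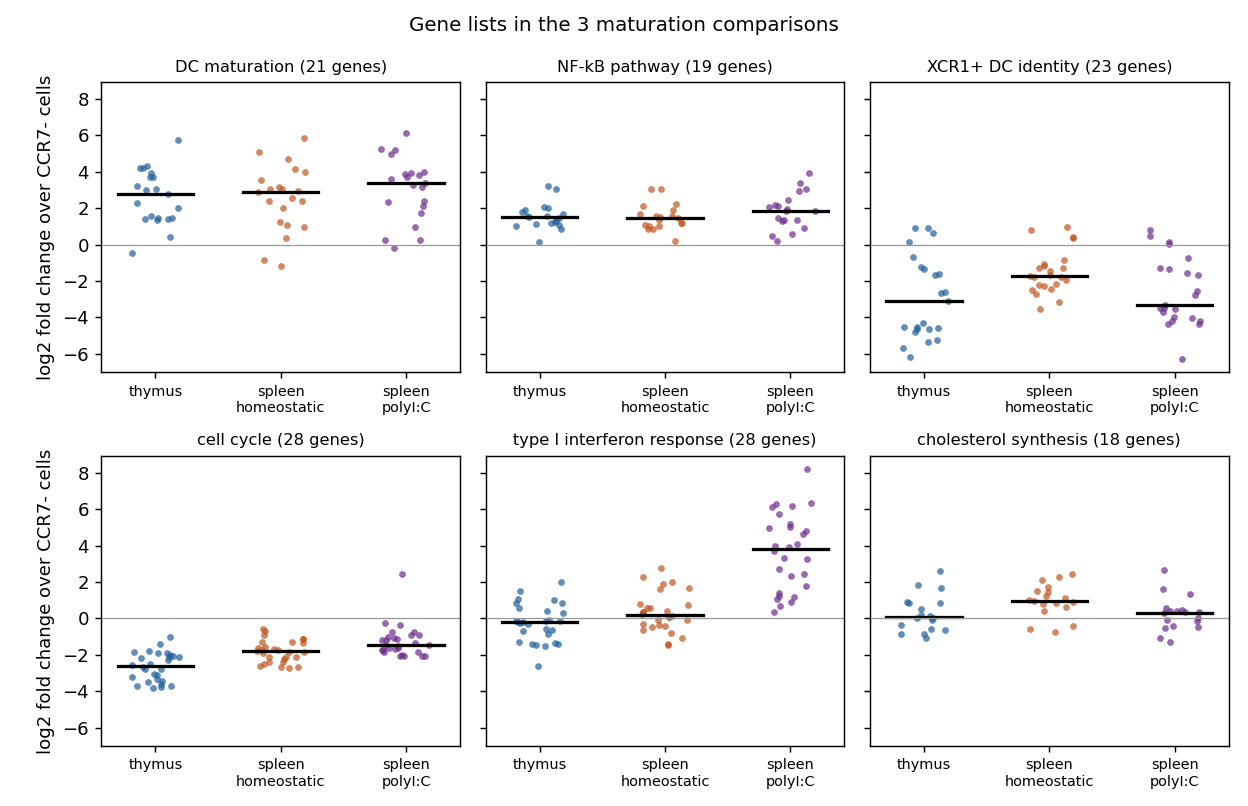
Log2 fold changes over CCR7- cells for the tested genes of 6 lists in the 3 maturation comparisons, 1 point per gene with the median as a bar. The median of the type I interferon response was 3.81 after polyI:C and 0.18 in untreated spleen, and that of the XCR1+ DC identity genes was -3.08 in thymus and -1.74 in untreated spleen.

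PolyI:C maturation shared most of its calls with homeostatic maturation. Of 4115 genes called in both spleen comparisons, 1341 were higher in both (309 for independent calls), 2721 lower in both (923) and 53 opposite (1076). Pearson's r across genes was 0.831 and Spearman's rho 0.820. The same 3 CCR7- arrays entered both sides and could not be divided, and simulated unchanged groups gave an average r of 0.483 and up to 0.829, close to the measured r. The covariance was 0.886, against a simulated average of 0.029 and at most 0.116. Thymic and polyI:C maturation, which shared no arrays, had r = 0.749, rho = 0.703 and a covariance of 0.913. Simulated r reached 0.777, above the measured one, and the simulated covariance averaged 0.001 and was at most 0.077. These simulations did not keep the resemblance between the tissues of CCR7- arrays with the same replicate number. These comparisons had 1505 genes higher in both, 2181 lower in both and 151 opposite (422, 781 and 1156 for independent calls).

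Set directly against untreated spleen CCR7+ cells, the polyI:C cells differed most in interferon-stimulated genes. Ifit1 (6.32), Ifit3 (5.80), Ifit2 (5.73), Oasl2 (5.73), Rtp4 (5.53), Plagl1 (5.37), Ramp3 (5.06) and Oas1a (5.04) were the highest. All 28 type I interferon response genes were higher, also 28 adjusted over the list alone, with a median of 3.21. The camera test gave the list an adjusted p = 5.08e-42, and adjusted p = 0.00828 with an estimated correlation. Jchain (-5.31), Igha (-4.79), Cdh2 (-4.48), Zmynd15 (-4.05), Hepacam2 (-3.76), Scube3 (-3.67), Pou2af1 (-3.61) and Fcrla (-3.31) were among the lowest. In all, 1169 genes were higher and 1317 lower, and without polyI:C replicate 3 the lower ones numbered 814. A fit of the compared groups only called 534 higher and 547 lower. Of 871 genes higher with polyI:C in both comparisons, 332 had also risen in homeostatic maturation, 46 had fallen and 493 had not been called. The calls for Jchain and Pou2af1 ended without spleen CCR7+ replicate 2 (-4.53 and -2.92), without polyI:C replicate 1 (-4.91 and -3.31) and without polyI:C replicate 3 (-4.35 and -3.02).

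Single costimulatory genes and cytokines differed between treated and untreated CCR7+ cells. Of 22 T cell ligands 9 were higher with polyI:C and 6 lower (10 and 6 adjusted over the list alone), and camera called neither this list (adjusted p = 0.0689, and adjusted p = 0.551 with an estimated correlation) nor the cytokines (adjusted p = 0.585, and adjusted p = 0.846 with an estimated correlation). Cd80 (4.01), Cd274 (1.82) and Cd86 (1.43) were higher with polyI:C and Ccl22 (-1.89) was lower, with 9 of 21 DC maturation genes higher and 2 lower (10 and 2 adjusted over the list alone). Ifnb1 (2.93), Il6 (2.03) and Osm (1.77) were higher and Il12b was lower (-3.07), and of 18 cytokines 6 were higher and 3 lower (6 and 6 adjusted over the list alone). Cxcl10 (3.77) and Cxcl11 (2.75) were higher and Ccl9 (-3.22) lower, with 2 of 16 chemokines higher and 6 lower (2 and 8 adjusted over the list alone). Iigp1 (4.29) and Igtp (3.60) were among 7 of 15 interferon gamma response genes that were higher, against 1 lower (9 and 1 adjusted over the list alone), and this list had a camera adjusted p = 3.9e-06, and adjusted p = 0.0185 with an estimated correlation. Lgals9 (2.34) was among 6 of 20 genes associated with tolerance that were higher, against 1 lower (7 and 2 adjusted over the list alone), and Axl (2.89) was among 3 of 19 uptake receptors that were higher, against 6 lower (3 and 6). Cholesterol synthesis genes were lower in 10 of 18 cases and higher in none (12 lower adjusted over the list alone), with Mvd at -1.41 and Insig1 at -1.25. Identity genes were lower in 13 of 23 cases and higher in 1 (15 and 1 adjusted over the list alone), including a fall in Cd36 (-3.07); without spleen CCR7+ replicate 1 none was higher. Egr1 (-1.95) was among 7 of 18 handling stress genes that were lower, also 7 adjusted over the list alone. The mean of this list relative to all arrays was -0.433, 0.311 and 0.738 in untreated CCR7+ replicates 1 to 3. With polyI:C it was -0.522, -1.023 and -0.51, so the size of this difference depends on the array. A difference in handling was not tested.

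Interferon-stimulated genes were prominent among the differences between immature cells of the tissues. Zmynd15 (6.26), Cldn1 (5.24), Klrb1b (4.74), Cd84 (4.66) and F11r (4.47) were highest in thymus CCR7- cells relative to spleen, and Ptgis (-4.60), Gp2 (-4.08), Serpinb2 (-4.06), Adgre4 (-3.54) and Ifitm6 (-3.47) were lowest. Of 28 interferon response genes 22 were higher in thymus, such as Oas1a (4.13), Xaf1 (3.51) and Rsad2 (3.45), and only Ifitm3 was lower (-1.20); adjusted over the list alone 23 were higher and 1 lower. The list's camera adjusted p = 6.17e-26, and adjusted p = 0.0486 with an estimated correlation. Cell cycle genes were higher in thymus in 14 of 28 cases and lower in none (23 higher adjusted over the list alone), with Cenpe at 2.22 and Cdc20 at 2.17. Spleen CCR7- replicate 1 stood apart in this list, with a mean of 1.38 relative to all arrays against 0.26 and 0.22 in the other spleen CCR7- arrays and 1.86 to 2.04 in thymus, so the size of this difference depends on the array. Ccl17 (2.96), Ccl22 (2.74), Lgals1 (3.13), Mgl2 (2.98) and Epcam (4.03) were also higher in thymus, whereas Aldh1a2 (-3.12), Hmox1 (-2.83) and Tlr13 (-1.41) were lower. Of 23 identity genes 3 were lower in thymus, including Cd8a (-2.11) and Cadm1 (-1.15), and 2 higher, including Itgae (1.20), or 5 and 2 adjusted over the list alone. Camera placed the list lower in thymus, with an adjusted p = 0.00224, and adjusted p = 0.573 with an estimated correlation. Of 16 macrophage and monocyte markers, Hmox1 among them, 5 were lower in thymus and 1 higher (6 and 1 adjusted over the list alone). Their camera adjusted p = 0.00037, and adjusted p = 0.471 with an estimated correlation, and a difference in macrophage content was not tested. In all, 671 genes were higher and 441 lower in thymus, and without thymus CCR7- replicate 3 the lower ones numbered 293. Arrays of the tissues with the same replicate number resembled each other, and with this number as a block in a fit of these groups only 1879 were higher and 1382 lower. Array weights gave 1142 and 846.

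Mature cells of the tissues differed in interferon response and identity genes, among others. Igfbp4, Flrt3 (3.96) and Ccl17 (3.75) were among the genes highest in thymus CCR7+ cells relative to untreated spleen CCR7+ cells, and Ctla2b (-5.48), Cd244a, Aldh1a2 (-4.16), Cd36 (-4.06) and Treml4 (-3.96) were lowest. Identity genes were lower in 17 of 23 cases and higher in none, also 17 adjusted over the list alone, with Naaa at -3.93 and Tlr3 at -3.59. The camera test of this list gave an adjusted p = 5.02e-19, and adjusted p = 0.0551 with an estimated correlation. Oas1a (3.12), Oasl2 (2.60) and Xaf1 (2.59) were among 19 of 28 interferon response genes that were higher in thymus, against 1 lower (22 and 1 adjusted over the list alone). Their camera test had an adjusted p = 6.49e-12, and adjusted p = 0.13 with an estimated correlation. Cd80 (2.55), Pdcd1lg2 (2.31) and Itgb8 (3.07) were higher and Cxcl9 (-2.91), Ccl9 (-2.37) and Marchf1 (-2.57) lower. Insig1 (-1.77) and Cyp51 (-1.23) were among 11 of 18 cholesterol synthesis genes that were lower, against none higher (13 lower adjusted over the list alone). In all, 1187 genes were higher and 473 lower, and without thymus CCR7+ replicate 2 the higher ones numbered 626. With the replicate number as a block in a fit of these groups only, the numbers were 1455 and 564, and in such a fit without the block 531 and 271.

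Transcripts typical of other cells were present in the sorted fractions. Rag1 (2.85), Cd3g (2.53) and Bcl11b (2.14) rose with maturation in thymus, where 9 of 14 thymocyte and T cell markers rose and none fell, also 9 adjusted over the list alone, against 2 of 14 in untreated spleen (2 adjusted over the list alone). Between mature cells of the tissues Rag1 differed by 6.29, and 8 of the 14 markers were higher in thymus (9 adjusted over the list alone). Cd79b rose by 2.62 in untreated spleen, with 6 of 11 B cell markers higher. In polyI:C against untreated CCR7+ cells its log2 fold change was -2.98, and 6 of 11 markers were lower (9 adjusted over the list alone). Against CCR7- cells it differed little, with 4.7, 6.2 and 4.3 in the polyI:C arrays and 5.1, 6.4 and 4.9 in spleen CCR7- arrays. These are the values of replicates 1 to 3. The mean of the B cell list relative to all arrays was 1.79 in spleen CCR7+ replicate 2, against 0.48 and 0.56 in replicates 1 and 3. In spleen CCR7- arrays it was -0.17 to 0.38, so the size of the rise depends on that array. Krt8 (2.41), Krt18 (1.71) and Epcam (1.78) were higher in thymic than in splenic CCR7+ cells, with 4 of 10 thymic epithelium markers higher and none lower (6 adjusted over the list alone). Spic rose (4.25) and Lyz2 fell (-4.43) after polyI:C, where 3 of 16 macrophage and monocyte markers rose and 7 fell, also 3 and 7 adjusted over the list alone. PolyI:C replicate 1 stood apart in this list, with a mean of 0.58 relative to all arrays against -0.18 and -0.35 in replicates 2 and 3. Klrk1 (2.18) and Gzmb (2.12) were higher with polyI:C than without, and these were the 2 of 9 NK cell markers called. Of the remaining lists of other cells, SIRPa+ DC markers had 3 of 10 lower and 1 higher in thymic maturation, plasmacytoid DC markers had 1 of 12 higher and 1 lower, and none of the 8 neutrophil and none of the 5 erythroid markers was called there.

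**Figure D4:**
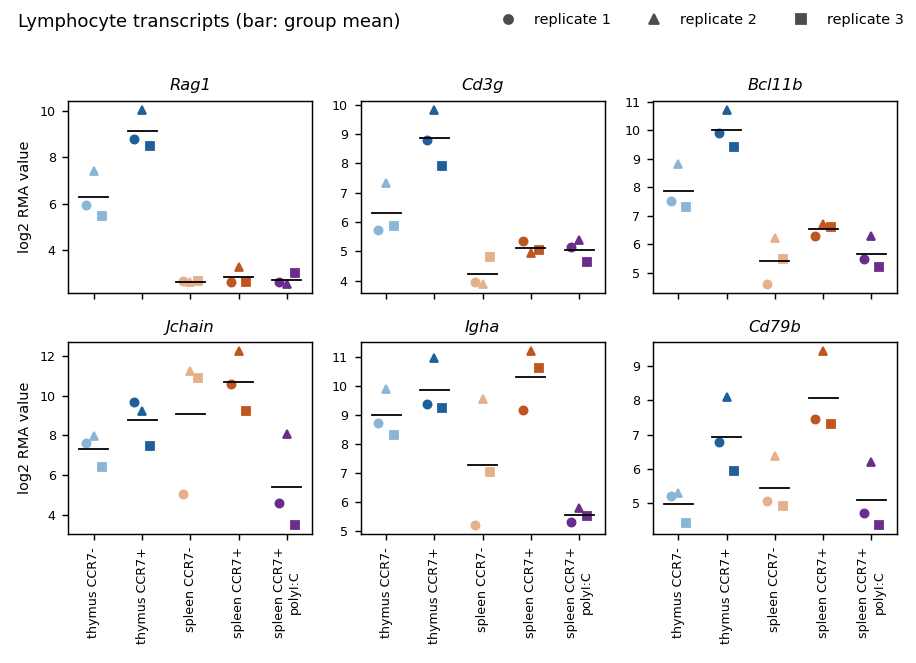
Log2 RMA values of 3 T-lineage and 3 B-lineage transcripts in each of the 15 arrays by group, with symbols for the replicate number and bars for the group mean. Rag1 had its highest value of the thymus CCR7+ cells in replicate 2, as did Jchain of the untreated spleen CCR7+ cells.

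Among the 217 tests of lists (31 lists in 7 comparisons), camera with its preset correlation called 88. With an estimated correlation 3 of these calls held, those of the type I interferon response in polyI:C against untreated CCR7+ cells and in immature thymus against spleen cells, and that of the interferon gamma response in polyI:C against untreated CCR7+ cells. The first principal component held 59.2% of the variance and the second 12.3%. Spleen CCR7+ replicate 1 stood apart in RNA quality, with a difference between the 3' and 5' Gapdh probe sets of 5.22 (log2) against 2.85 to 4.02 in the other 14 arrays. The untreated spleen CCR7+ arrays also varied most, with median absolute deviations from the group of 0.160 to 0.209 against 0.103 to 0.158 elsewhere.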

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

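All tests of explanations in this part were chosen after the results they concern had been seen. The results below were picked out because the change with maturation differed between thymus and spleen in a test of that difference.

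The change was more positive in thymus for 244 genes and more negative for 189. Without thymus CCR7- replicate 3 these were 143 and 120. The more positive ones were 156 without thymus CCR7- replicate 2, 145 without thymus CCR7+ replicate 2, 158 without thymus CCR7+ replicate 3 and 159 without spleen CCR7- replicate 3, and the more negative ones were 125 without thymus CCR7+ replicate 3. When tissue was reassigned at random among the arrays of each state, 4 of 100 drawn reassignments, the real one included, called as many genes as the real 433, and the highest other called 507. Over all 200 possible reassignments 8 did, and the highest called 2310. That one exchanged thymus and spleen among the CCR7- arrays alone, which puts the overall difference between the tissues into the tested term, a structure of the samples rather than of maturation. The 162 reassignments that mixed the tissues in both states called at most 7 genes. Arrays with the same replicate number resembled each other between the tissues, and reassignments that part all such pairs were not counted apart.

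The differences of single genes (thymus change minus spleen change, log2) were positive for Igfbp4 (4.54), Serpinb2 (4.14), Flrt3 (3.60), Stat4 (3.44), Ramp3 (3.40), Ndnf (3.24), Rag1 (2.65), Ido1 (2.62), Cd80 (2.41), Cd274 (1.92) and Gbp2 (1.38). They were negative for Zmynd15 (-4.74), Cd244a (-4.34), Klrb1b (-3.83), Naaa (-3.59), Cd36 (-3.36), P2ry14 (-2.79), Rab7b (-2.57), Ccl9 (-2.44), Cd207 (-2.32), Cxcl9 (-2.24), Usp18 (-2.20), Mgl2 (-2.12), Insig1 (-1.75) and H2-DMa (-1.40). For Klrb1b and Mgl2 in spleen and Serpinb2 in thymus the CCR7- cells were near or below the filter value of 4.39, so that a fall there could not be seen and these 3 differences say little about maturation. Rag1 lay below that value in spleen CCR7- and CCR7+ cells, where its change was 0.20. Its difference therefore sets a rise in thymus beside background signal in spleen. The call for Rag1 ended without spleen CCR7- replicate 1 (2.65), 2 (2.66) or 3 (2.65), spleen CCR7+ replicate 1 (2.55) or 3 (2.53), thymus CCR7- replicate 1 (2.50) or 3 (2.24), or thymus CCR7+ replicate 2 (2.18), and in a fit of the compared groups only (2.65). That for Cd274 ended without spleen CCR7- replicate 2 (1.85) or 3 (1.89), thymus CCR7- replicate 2 (1.92) or 3 (1.86), or thymus CCR7+ replicate 1 (1.86), 2 (1.96) or 3 (1.94). Among the lists, camera called the XCR1+ DC identity genes (median -1.30), the type I interferon response (-0.47), chemokines (-0.32), cell cycle (-0.85), cholesterol synthesis (-0.73), ER stress and secretion (-0.25), and the thymocyte and T cell markers (0.88). None of these list calls held with an estimated correlation, where the adjusted p-values ran from 0.152 to 0.826.

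Identity genes fell less in spleen than in thymus. Degraded RNA in spleen CCR7+ replicate 1, the array with the largest Gapdh difference between probe sets, is argued against as the cause. A smaller fall needs high identity values in that array, and its list mean was the lowest of its group, with a difference of -0.67 from the other 2. The median difference of the list was -1.26 without that array and -1.30 with it. A share of CCR7- cells left in the spleen CCR7+ sort stays open. The 8 largest spleen falls, plus 2 standard errors, allow a share of at most 13.3% (Serpinb2) to 25.4% (Hcls1) of CCR7- RNA. The lowest of these limits binds if all genes are diluted alike. Of the 19 identity genes lower in thymus, 12 would need more than that lowest limit, 4 of them by more than 2 standard errors, and 5 more than the highest, with Cd36 needing 38.3% and a median of 16.9%. The lowest limit rests on 1 gene and most of the excesses lie within 2 standard errors, so this does not decide. A difference between the tissues themselves, which the design names, was not tested apart from these and stays open.

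Thymocyte and T cell markers rose in thymic CCR7+ cells. An equal rise with maturation in both tissues stays open. All 14 tested markers had the more positive change in thymus, but they vary together (estimated correlation 0.552), and the camera test of the difference gave the list adjusted p = 0.667 with that estimated correlation. Replicate 2 had the highest list mean in both thymus fractions, with 0.571 in CCR7- cells (-0.186 and -0.164 in replicates 1 and 3) and 2.084 in CCR7+ cells (1.087 and 0.951). The fit did not pair arrays by number, so this shared level entered the estimated correlation and weakened the test. Of the 9 markers called in thymus, 2 were also called in untreated spleen. Thymocyte RNA or cells carried through the sort may have contributed. Of the 14 tested markers, 13 had their highest thymus CCR7+ array in replicate 2, and all 14 had it in replicate 2 of the thymus CCR7- cells. At the estimated correlation these count as about 1 independent marker, so the number decides nothing. Carried cells would themselves raise that correlation, so this test could not have decided. Rag1 stood at 8.8, 10.1 and 8.5 in thymus CCR7+ replicates 1 to 3, and Cd3g at 8.8, 9.8 and 7.9. Markers that share 1 regulator would also move together, the CD11c+ gate would remove free T cells but not cells bound to DCs or RNA taken up by them, and a true expression by thymic DCs was not tested.

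B-lineage transcripts were lower after polyI:C than in untreated spleen CCR7+ cells. They were 6 of the 11 tested B cell markers and Jchain, Igha and Pou2af1, which are in no list and were added after their values were seen. Spleen CCR7+ replicate 2 alone is argued against as the cause of all of it, since 5 of the 11 markers were called lower without it, 4 of them among the 6. The median of the 11 was -0.69 without it and -1.19 with it, and the calls for Cd79a and Blk ended, so a part from that array stays open. B-lineage RNA or cells in the sort are a candidate source that the values did not decide. All 11 markers had their highest untreated CCR7+ array in replicate 2, and 7 had it in replicate 2 of the spleen CCR7- cells, but with an estimated correlation of 0.69 they count as about 1 independent marker. B-lineage cells in the sort would themselves raise that correlation, so this test could not have decided. Cd79b stood at 7.5, 9.4 and 7.3 in the untreated CCR7+ arrays, above its 5.1, 6.4 and 4.9 in the spleen CCR7- arrays. Ighm stood at up to 12.8 in the former and at 10.7, 12.7 and 12.3 in the latter. Fcrla was lower in the CCR7+ arrays (8.6, 9.4 and 9.1) than in the CCR7- arrays (9.3, 10.2 and 9.9). The transcripts thus did not move together between the untreated fractions, and 1 source for all of the falls was not shown. The gate on CD11c would remove most B cells. A direct effect of polyI:C on these transcripts was not tested.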

How the results depend on the processing

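The fit of the compared groups with the replicate number as a block, and the list tests without spleen CCR7+ replicate 1, were chosen after seeing the data; the other alternatives were fixed before the data were examined. Overlaps between the maturation comparisons stayed within 1.5 times their values under the alternatives run for them. These were the filters, the mean of probe sets, repeated quantile normalisation, the replicate block and each array left out. Under the same alternatives no correlation moved by more than a spread computed from its values with each array left out. For single arrays left out this was all but fixed in advance, since the spread comes from those same values. It therefore does not show how far the correlations depend on single arrays.

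A test against a log2 fold change of 1 asks for larger changes by construction and called fewer genes. It called 542 higher and 602 lower in thymic maturation, 369 and 259 in homeostatic and 696 and 1073 in polyI:C maturation of the spleen, 141 and 52 for polyI:C against untreated CCR7+ cells, 82 and 46 between immature and 64 and 60 between mature cells of the tissues, and 13 and 16 for the difference between tissues.

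A fit of the compared groups only, which has fewer arrays for the spread, called 534 higher and 547 lower for polyI:C against untreated CCR7+ cells and 531 and 271 between mature cells of the tissues. Both comparisons include untreated spleen CCR7+ cells, whose arrays differed most among themselves. Their lowest correlations within the group were 0.962 to 0.965, against 0.979 to 0.990 in the other groups. The main fit shares 1 estimate of the spread, which can understate that of this group. Counts of homeostatic maturation, which also includes it, stayed within 1.5 times. The cause was not tested. Array weights gave 1142 and 846 between immature cells and 284 genes with a more negative change in thymus; the cause was not tested.

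With the replicate number as a block in the fit of all arrays, the 14 counts stayed within 1.5 times. Between immature cells 706 genes were higher and 495 lower, and between mature cells of the tissues 1264 and 511. This block gives each number the same shift in all 5 groups. Arrays with the same number did not resemble each other between the states, with correlations of 0.04, -0.06 and 0.16 in thymus. It could therefore not take up a resemblance that held only between the tissues within a state. With the block in a fit of only the compared groups, 1879 were higher and 1382 lower between immature cells. That block does take up what arrays with the same number share between the tissues. Whether this accounts for the larger counts was not tested. No fit paired in this way was run for the difference between tissues.

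With single arrays left out, genes lower with polyI:C than in untreated CCR7+ cells ranged from 814 (without polyI:C replicate 3) to 1547, genes lower in immature thymus than spleen cells from 293 (without thymus CCR7- replicate 3) to 361, and genes higher in mature thymus than spleen cells from 626 (without thymus CCR7+ replicate 2) to 1505. Genes with a more positive change in thymus ranged from 143 (without thymus CCR7- replicate 3) to 358, and those with a more negative one from 120 (without the same array) to 217. Every group then had at least 2 arrays.

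Of 88 list calls by camera, 3 held with an estimated correlation. Without spleen CCR7+ replicate 1, 7 of the 217 list tests lost their call and 3 gained one. Of the 286 gene values with a comparison named in the text, 280 were called; 5 lost the call with some single array left out, 3 under another alternative and 58 under the test against a log2 fold change of 1, 1 gained it and none reversed. These genes had been chosen partly for keeping their calls. Of all 683 called pairs of gene and comparison that the rule chose, 134 lost the call with some single array left out, 5 of them among the 263 printed and 129 among the 420 not printed. No value could be given for 2 under the 60th percentile filter and for 27 without _s_at, _x_at and _a_at probe sets. Probe sets of 1 gene differed widely for some named genes besides Igfbp4, though none of the following was called the other way. They ran from 0.43 to 6.22 for Dscaml1 in homeostatic maturation. In polyI:C maturation they ran from -5.77 to -0.28 for Slc9a9 and from -4.91 to 0.07 for Egr3. Those of F11r ran from 0.09 to 4.47 between immature cells, and those of Cd80 from 0.25 to 4.01 between treated and untreated CCR7+ cells. Arrays have no counts, so their signal over background sets the limit: a change in a gene near background is compressed and can be missed.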

Other observations

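All tests in this part were chosen after the results they concern had been seen. For the 6 comparisons of 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, called as many genes. Thymic maturation called 5079 genes and the highest other split 1, homeostatic maturation of the spleen 4969 and 2, polyI:C maturation 6329 and 0, and polyI:C against untreated CCR7+ cells 2486 and 18. Immature cells of the tissues gave 1112 and 1, and mature cells 1660 and 0. All 3 replicate numbers pair the arrays only between the tissues, and there the other splits that part all 3 pairs called at most 0 genes for immature and 0 for mature cells. Replicate 2 of the polyI:C and of the untreated spleen CCR7+ cells also resembled each other, with a correlation of 0.64 after removing group means.

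Across tissues and states, the mean of the thymocyte and T cell markers was highest in replicate 2 in 4 of the 5 groups and in replicate 1 after polyI:C, and that of the B cell markers was highest in replicate 2 in all 5 groups. The titles do not say whether arrays with 1 number share a sort day.

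Xcr1, the gene in the name of the cells, stood at 11.40 in thymus and 11.58 in spleen CCR7- cells, and at 5.25, 8.03 and 7.54 in thymus, untreated spleen and polyI:C CCR7+ cells. As XCR1 was not among the sort gates given, a change of the transcript and a change of the cells sorted cannot be told apart.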
